A study of Homo sapiens with 3 samples.

How the data were processed

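RNA of 3 cultures of IMR-90 ER:Ras human fibroblasts was measured on 1 array each: growing cells, cells in oncogene-induced senescence (OIS) after 6 days in 100 nM 4-OHT, and cells in replicative senescence (RS) after 10 weeks of repeated passage. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled cRNA was prepared by the standard Affymetrix procedure. The deposited values are a linear intensity per probe set, made with MAS5 per the submitters' processing notes, and the version and settings are not given in the sources used here. MAS5 subtracts background, combines the probes of a set and scales each array by a single factor. The 2% trimmed mean was 499, 498 and 498 on the growing, OIS and RS arrays, so the arrays had been brought to a common mean. No detection calls were used here. A shift of all genes in 1 direction would be removed by such scaling, and every ratio is relative to the average probe set. The table held 54613 probe sets and none with a control name.

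Genes were named from the platform annotation given with the values. A single gene was named by 41091 probe sets, several genes by 1801 and none by 11721, and only the first group was used for genes. Of these, 41037 had a gene identifier found in the RefSeq table, and none needed a newer symbol. That table served only for symbols, chromosomes and neighbouring genes. No genome build is attached to the values, so no coordinates are given. All sample groups were taken from the labels, and no column was left unmapped.

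The following choices were made before the data were examined: the comparisons, the floor, the gene rule, the 2-fold size, the named-gene rule, the gene lists and the alternatives. Values below the pooled median of the 3 arrays, 45.5, were raised to it before log2 was taken. A gene was represented by its probe set with the highest mean log2 value over the 3 arrays, and counted as measured when above the floor on at least 1 array, which held for 13466 of 19775 genes (68.1%). Log2 ratios were formed for OIS over growing, RS over growing and OIS over RS, and genes at or past 2-fold were counted. With 1 array per condition there are no residual degrees of freedom, so no p-value or standard error between conditions is given. Where a gene has other probe sets above the floor, the spread between its best 2 was used to describe probe error. Probe sets whose names end in _s_at or _x_at can hybridize to several transcripts, of the same or of other genes, and are called cross-hybridizing. Those used for genes name 1 gene in the annotation, so the ending alone does not show that another gene was read.

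Named genes were the 10 with the largest and the 10 with the smallest ratio in each comparison among genes above the floor on both arrays whose other probe sets had the same sign. Added to these were 14 fixed genes and, for each list described, the 2 highest and 2 lowest members with single further members. Genes of the Y chromosome and XIST were left out of this rule. In all 43 gene lists, including markers of other cell types, were scored by the median log2 ratio of their measured genes if at least 5 were measured, which held for 42. The median was placed as a percentile among 10000 random lists of the same size drawn from measured genes in 10 bins of mean log2 value. A list stood apart below percentile 2.5 or above 97.5, which describes these arrays and is no test of the conditions.

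The overlap of the OIS and RS differences was set against independent lists and against 100 simulations of unchanged arrays sharing 1 growing array. Alternatives were quantile normalization, centring each ratio on its median, a floor at the 25th percentile (11.7) or 60th percentile (88.8), no floor with a pseudocount of 16, no filter on low values, the median of all probe sets of a gene, leaving out cross-hybridizing probe sets, and 3-fold in place of 2-fold. The steps were tested on simulated data modelled on OIS against growing cells, with 12685 genes measured and noise of 0.25 log2 units per array. At 3-fold, 48 of 50 higher and 45 of 50 lower genes were called, at 6-fold 50 of 50 and at 1.5-fold 9 of 50, while 50 of 12485 unchanged genes were called. The changed genes were drawn only from genes far above the floor on all 3 arrays, and differences between cultures were not simulated. These rates therefore describe the steps and not the deposited data. Of lists without a shift 5 of 200 stood apart, and of lists shifted by 0.5 all 50 did. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.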

Results

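The data comprised 3 expression microarrays of IMR-90 cells, an established line of normal human lung fibroblasts, in a derivative named ER:Ras for the inducible Ras protein it carries. In such fusions Ras is joined to the hormone-binding part of the estrogen receptor and is switched on by 4-hydroxytamoxifen (4-OHT). One condition was growing cells with no treatment. The second, oncogene-induced senescence (OIS), was brought on by 6 days in 100 nM 4-OHT. The third, replicative senescence (RS), was reached over 10 weeks of repeated passage. Senescence is a lasting arrest of cell division in which cells stay metabolically active.

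Each condition had 1 array and none had a replicate, so no test between conditions was possible, and the number of arrays limits the precision of every value. The arrays were alike in scale: of 54613 probe sets, 50.3% were above the floor of 45.5 signal units in growing cells, 49.9% in OIS and 49.8% in RS. The median signal was 46.2, 45.3 and 44.9 in that order. Of 19775 named genes, 13466 were above the floor on at least 1 array and count as measured below. The only repeat measurement was a second probe set of the same gene on the same array, available for 6759 genes. The log2 ratios of these pairs had an SD of 0.36 for OIS over growing cells, 0.33 for RS over growing cells and 0.37 for OIS over RS, which covers probe error but not differences between cultures. A fold preceded by "at least" has the dimmer array at or below the floor.

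The first comparison set OIS against growing cells and asked which genes differ in the culture kept 6 days in 4-OHT. OIS cells had far lower mRNA of the machinery of DNA replication and mitosis and far higher mRNA of inflammatory secreted proteins. All 40 measured G2/M and mitosis genes were at least 2-fold lower, and 16 of 24 measured cytokine and chemokine genes were at least 2-fold higher. Among genes above the floor on both arrays whose other probe sets had the same sign, PTGS2 had the highest ratio. The signal of PTGS2, the prostaglandin-forming enzyme cyclooxygenase-2, was 96.5 in growing cells and 19178 in OIS, 199-fold higher. Across all measured genes 663 were at least 2-fold higher in OIS and 893 at least 2-fold lower, of which 183 and 213 passed 4-fold.

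Ratios were ranked only among genes above the floor on both arrays whose other probe sets had the same sign. Folds given as "at least" were thus not ranked. Among the 10 largest ratios so ranked of OIS over growing cells, 6 were of cytokines or chemokines. CXCL3 was 180-fold, CXCL1 132-fold and CXCL5 85.2-fold higher, and all are chemokines that attract neutrophils. The growing signal of CXCL3, 50.6, was near the floor, and with the floor at the 60th percentile its log2 ratio was 6.68 in place of 7.49. IL1A and IL1B, the alpha and beta forms of interleukin-1, were 120-fold and 76.2-fold higher. TNFSF15, a cytokine of the tumor necrosis factor family, was 108-fold higher. The others were PTGS2, C11orf96 at 62.7-fold, COL10A1, the collagen of hypertrophic cartilage, at 55.2-fold, and BCL2A1, a survival protein of the BCL2 family, at 38.7-fold. IL6, fixed in advance as a marker of the senescence secretome, was 19.8-fold higher at a signal of 14925, and the chemokine CXCL8 was 17.3-fold higher at 30857.

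The secreted cytokine and chemokine list had a median log2 ratio of 2.97, above every one of 10000 random lists of matched signal. Its largest ratios were CXCL3 and CXCL2, the latter at least 167-fold higher, while CCL20 was at least 100.2-fold and CXCL6 at least 98.1-fold higher. The 1 member past 2-fold in the other direction was CXCL12, a chemokine made by stromal cells, at least 12.0-fold lower, and IL15 was 1.60-fold lower. Of the 20 measured NF-kappaB feedback and target genes 13 were at least 2-fold higher and none lower, with a median of 1.22. The cell adhesion molecule ICAM1 was 12.4-fold and NFKBIZ, a nuclear regulator of NF-kappaB, 13.7-fold higher, while TNFAIP8 was 1.34-fold lower and VCAM1 1.04-fold higher. Secreted proteases and their inhibitors had a median of 0.69, with 5 of 18 at least 2-fold higher and 1 lower. The matrix metalloproteinases MMP3 and MMP10 were 14.5-fold and 13.0-fold higher, ADAMTS1 was 2.19-fold lower and the inhibitor TIMP3 1.24-fold lower. Of 29 growth factors and IGF-binding proteins 11 were higher and 1 lower, with a median of 0.61. The EGF receptor ligand EREG was 19.6-fold higher, IGFBP1 at least 25.6-fold and BMP2 16.5-fold higher, whereas FGF7 was 2.56-fold lower. All 3 medians lay above every random list.

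Genes that respond to Ras and MAPK signaling were higher in OIS, with 16 of 28 at least 2-fold higher, 1 lower and a median of 1.17 above every random list. DUSP4 and DUSP6, phosphatases that switch off MAP kinases, were 29.8-fold and 4.04-fold higher, and the transcription factor EGR3 was at least 28.3-fold higher. FOSL1 was 2.18-fold lower and MYC 1.25-fold lower. In the AP-1 and immediate early list 8 of 19 were higher and 2 lower, with a median of 0.54 at percentile 99.99. IER3 was 5.11-fold higher, FOS at least 4.72-fold higher and KLF4 3.49-fold lower. Interferon-stimulated genes had a median of 1.07, above every random list, and 19 of 33 were at least 2-fold higher. IFI27 was 13.8-fold and the antiviral GTPase MX1 at least 9.16-fold higher, while IFIT2 was 2.06-fold lower. TGF-beta target genes had a median of 0.62, above every random list, with 5 of 17 higher. The Notch list had a median of 0.24 at percentile 95.2, inside the central range, yet its target HEY1 was 11.8-fold and HES1 4.79-fold higher and the receptor NOTCH2 2.32-fold lower.

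The cell cycle inhibitors differed in degree. CDKN2B, which encodes p15, was 9.93-fold higher in OIS, CDKN1A, which encodes p21, 2.60-fold, and CDKN2A, the locus of p16 and ARF, 2.40-fold, while CDKN1B was 1.80-fold and CDKN2D 1.59-fold lower. The list of 6 measured inhibitors had a median of 0.67 at percentile 99.7. Of 24 measured p53 targets 5 were at least 2-fold higher and none lower, with a median of 0.37 at percentile 99.96. GDF15, a stress-responsive secreted factor, was 13.7-fold higher, PLK3 3.55-fold higher, SESN2 1.24-fold lower and POLH 1.22-fold lower. BCL2 family genes had a median of 0.27 at percentile 98.2, with BCL2A1 and MCL1 higher by at least 2-fold, MCL1 at 2.32-fold, and BCL2 itself 2.08-fold lower. That position was lost after quantile normalization, at percentile 95.5.

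Genes of cell division were the lowest group in OIS. G2/M and mitosis genes had a median log2 ratio of -2.91, S phase genes of -2.03 and homologous recombination and Fanconi genes of -2.07, each below every random list. At least 2-fold lower were 36 of 43 S phase genes and 12 of 14 recombination genes. CDT1, which licenses replication origins, was 21.5-fold lower, although a second probe set of the gene gave a log2 ratio of only -0.44. The mitotic checkpoint kinase BUB1B was 12.4-fold lower, CDC20, an activator of the anaphase-promoting complex, 11.1-fold, and the repair gene RAD51AP1 7.33-fold lower. The proliferation marker MKI67 was 5.69-fold lower. CCNE1, which encodes cyclin E1, was 1.04-fold higher. Outside these lists, the genes among the 10 lowest ratios so ranked began with OXTR, the oxytocin receptor, 18.0-fold lower, and ZNF367, 16.5-fold lower. CEMIP, a protein of hyaluronan breakdown, was 15.5-fold, TOX 14.1-fold and the kinetochore protein SPC25 13.0-fold lower. The spindle motor KIFC1 and the noncoding RNA LINC01279 were each 11.7-fold lower.

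Nuclear structure genes were lower as well. LMNB1, which encodes lamin B1, was 9.25-fold lower, and the chromatin protein HMGB2 6.08-fold. In their list 8 of 28 were at least 2-fold lower, none higher, and the median was -0.45, below every random list, with HMGA2 at 1.48-fold and SYNE1 at 1.34-fold higher. KMT5A, the H4K20 monomethyltransferase, was 2.18-fold lower and EZH2, the H3K27 methyltransferase of Polycomb complex 2, 3.50-fold lower. Among 27 histone lysine methyltransferases 5 were at least 2-fold lower and none higher, including NSD2 at 3.51-fold lower, while SMYD3 was 1.22-fold and KMT5B 1.08-fold higher. The list median of -0.27 at percentile 3.03 lay inside the central range, but below it under 3 alternatives, at percentile 2.43 after quantile normalization and 1.66 with a lower floor. Polycomb genes had a median of -0.17 at percentile 11.9, with JARID2 2.43-fold higher and PHF19 2.26-fold lower beside EZH2.

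Lysosome, autophagy, stress response, collagen and contractile genes were shifted by smaller amounts. Lysosome genes had a median of 0.41, above every random list, with 5 of 36 at least 2-fold higher and none lower, among them the cathepsins CTSS at 12.8-fold and CTSK at 5.31-fold, while SMPD1 was 1.27-fold and LIPA 1.23-fold lower. Autophagy genes had a median of 0.36 at percentile 99.99 with none of 24 past 2-fold, and MAP1LC3B was 1.89-fold and ATG4A 1.81-fold higher. Without probe sets that can cross-hybridize the autophagy list was at percentile 94.8. The unfolded protein response list had a median of 0.40, also above every random list, with 4 of 28 higher, including the stress sensor ERN1 at 2.74-fold and DNAJB9 at 2.43-fold, whereas ASNS was 1.51-fold lower. Collagens had a median of 0.30 at percentile 99.8, with 5 of 24 higher and 2 lower. COL10A1 and COL4A6, at 4.23-fold, were the highest, and COL15A1 was 4.45-fold and COL14A1 at least 2.01-fold lower. NRF2 and antioxidant genes had a median of -0.27 at percentile 0.1, with AKR1C3 2.51-fold and AKR1C1 2.25-fold lower and SOD2 1.99-fold higher. Contractile and cytoskeletal genes had a median of -0.19 at percentile 0.25, with CNN1 2.25-fold and TAGLN 2.09-fold lower and CALD1 1.14-fold higher. Without the cross-hybridizing probe sets that list was at percentile 3.62.

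Much of core metabolism and protein synthesis lay inside the range of random lists in OIS. The medians were 0.15 for complex I, 0.11 for complexes II to V, -0.02 for the tricarboxylic acid cycle, -0.03 for fatty acid oxidation and 0.16 for cholesterol synthesis. For glycolysis the median was 0.19 at percentile 96.3, with HK2 at 4.43-fold, PFKFB3 at 3.01-fold and PFKFB4 at 2.30-fold higher, and this list stood above the range under 4 other settings. Cytosolic ribosomal protein genes had a median of 0.08, mitochondrial ribosomal protein genes of -0.03, ribosome biogenesis genes of -0.03, aminoacyl-tRNA synthetases of 0.07, proteasome subunits of 0.10 and heat shock proteins of 0.02. After quantile normalization the cytosolic ribosomal median was -0.02. The heat shock protein CRYAB was 4.21-fold lower in OIS. Other extracellular matrix genes had a median of 0.00, with the secreted factor CCN4 3.29-fold and MFAP2 2.71-fold higher, and EFEMP1 4.14-fold and decorin (DCN) 2.59-fold lower.

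Markers of other cell types gave no common direction in OIS. Fibroblast markers had a median log2 ratio of 0.09 at percentile 68.1, although PDPN, a membrane glycoprotein, was 9.94-fold higher. Blood cell markers had a median of -0.08, epithelial markers of -0.04 and neural markers of -0.26. Of 5 measured endothelial markers 3 were at least 2-fold higher, ROBO4 at 5.47-fold, PECAM1 at 2.76-fold and VWF at 2.19-fold, and the median of 1.13 stood at percentile 99.9. That position ended when genes below the floor were counted too, with a median of 0.00, and with all probe sets of each gene, at percentile 93.4. The adipocyte list had 4 measured genes and was not scored, but PPARG was 10.9-fold lower. HRAS had a single usable probe set and was 1.53-fold higher in OIS. GLB1, fixed in advance as the senescence-associated beta-galactosidase gene, was not analysed here because its probe set also names a neighbouring gene.

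In all, 16 of 42 scored lists stood above and 6 below the range of random lists in OIS. If genes varied independently, 1.05 on each side would do so. Genes of a list need not vary independently and some lists share members, so that number is no measure of chance here. A second probe set gave the same sign for 91.8% of 765 genes past 2-fold, and passed 2-fold itself for 56.7%. In the median of all probe sets, those below the floor on both arrays count as 0.00. That median can thus be small because other probe sets are dim. With the median of all probe sets of a gene in place of the brightest, the log2 ratio was -0.51 for KMT5A, -1.30 for HMGB2, 3.45 for IL1A, -1.97 for CEMIP, -1.96 for TOX, 2.27 for CDKN2B and 5.26 for CXCL8. With cross-hybridizing probe sets left out it was 0.91 for C11orf96, 1.28 for CXCL5 and -0.48 for KMT5A, and 0.00 for IL1A, CEMIP and HMGB2, whose other probe set was below the floor, so of these genes only CXCL5 kept its 2-fold call.

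**Figure D1:**
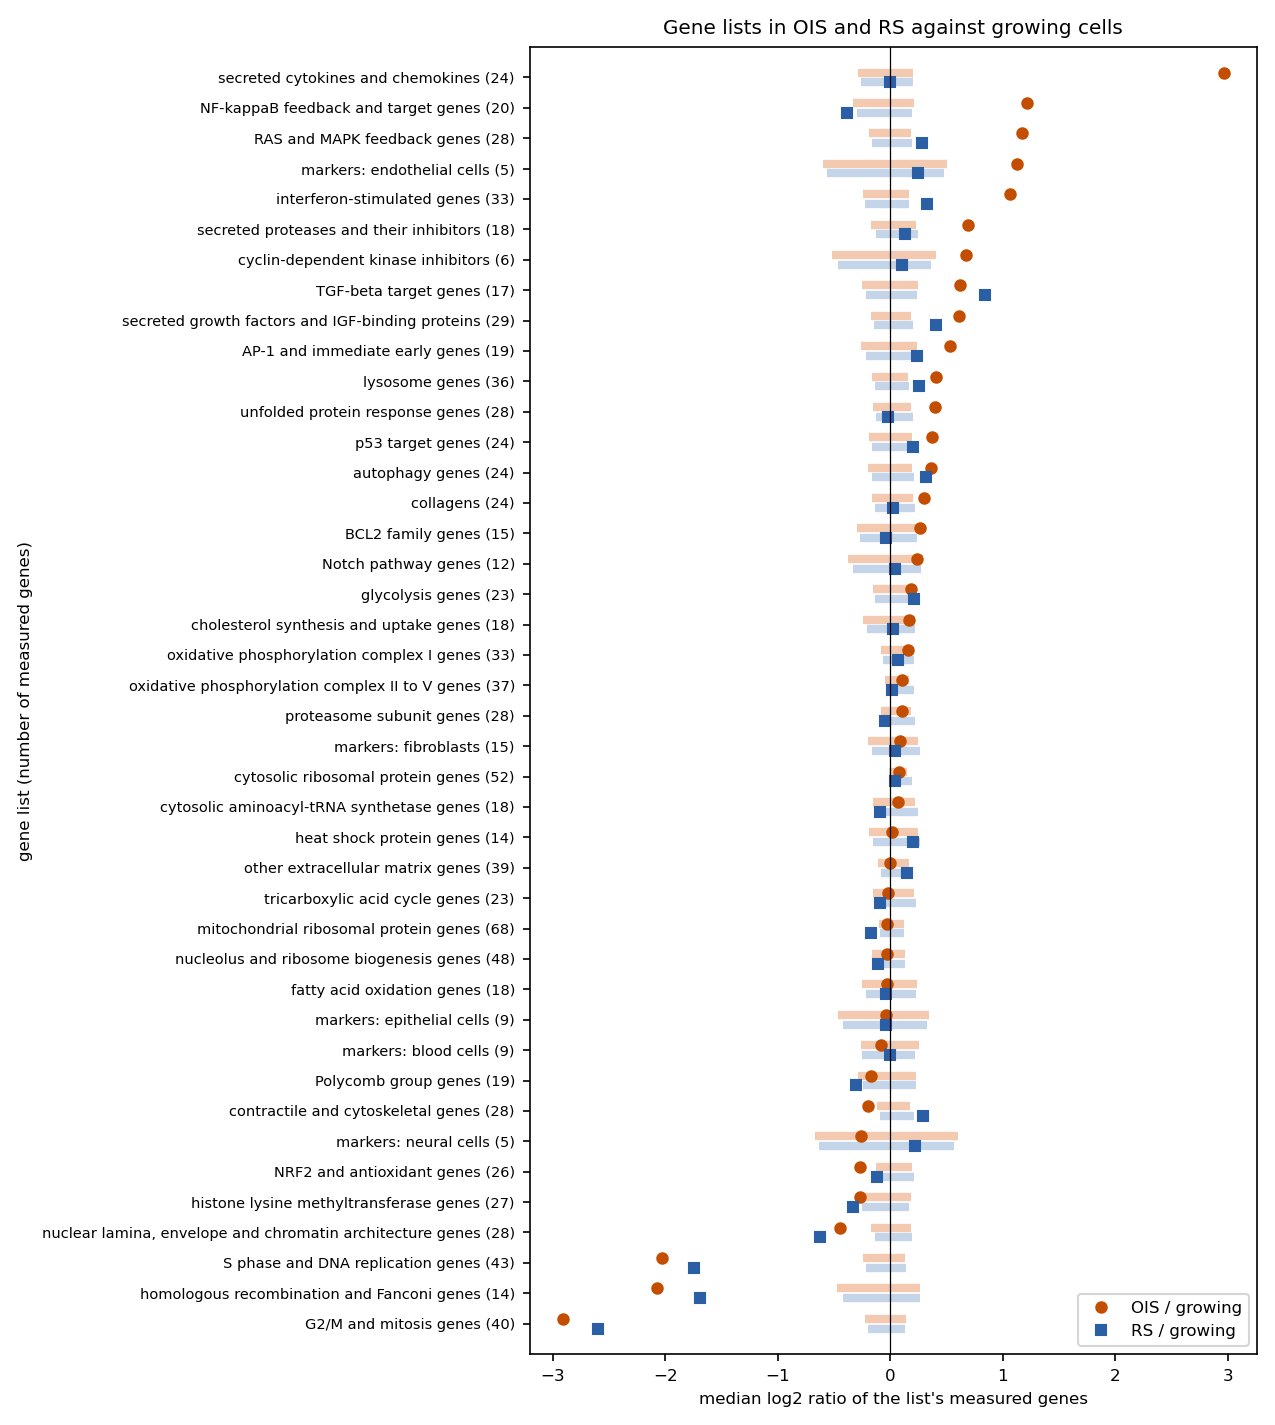
Median log2 ratio of each scored gene list for OIS over growing cells (circles) and RS over growing cells (squares), with the central range of random lists of matched signal as pale bars and the number of measured genes in parentheses. Cytokine genes lie at 2.97 in OIS and 0.00 in RS, and G2/M genes lie at -2.91 and -2.60.

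The second comparison set RS against growing cells and asked which genes differ once repeated passage has exhausted division. RS cells shared the low levels of replication, mitosis and nuclear lamina genes, but cytokine genes as a group were not higher. At least 2-fold lower were 39 of 40 G2/M genes and 36 of 43 S phase genes, while only 2 of 24 cytokine genes were at least 2-fold higher. Contractile and cytoskeletal genes as a group were higher, with a median log2 ratio of 0.29. In RS 501 genes were at least 2-fold higher and 751 at least 2-fold lower, with 74 and 169 past 4-fold.

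Ranked by the same rule, the 10 largest ratios of RS over growing cells began with TMEM178B, 38.9-fold higher. Its signal was 56.3 in growing cells and 2193 in RS. ANKRD1, an ankyrin repeat protein of stretched muscle, was 31.3-fold higher. Both genes were near the floor in growing cells. With the floor at the 60th percentile the log2 ratio was 4.63 in place of 5.28 for TMEM178B and 4.28 in place of 4.97 for ANKRD1. DNER, a transmembrane protein with EGF repeats, was 13.2-fold, CCND2, which encodes cyclin D2, 12.9-fold and the teneurin TENM1 12.7-fold higher. ACTC1, cardiac alpha actin, was 9.99-fold, the sialomucin PODXL 8.95-fold, the secreted protein SCUBE3 8.77-fold, COXFA4L3 8.16-fold and the actin-associated protein SYNPO2 8.14-fold higher. Other probe sets gave log2 ratios down to 1.64 for CCND2 and 0.67 for SCUBE3. The lowest ratio so ranked was of POSTN, the matrix protein periostin, at 11197 in growing cells and 412 in RS, 27.2-fold lower. The mitotic kinesin KIF20A was 15.6-fold, SPC25 12.0-fold, the spindle protein DLGAP5 11.1-fold, GAS2L3 10.2-fold and the centrosome kinase NEK2 9.84-fold lower. NPTX1, a neuronal pentraxin, was 11.4-fold, TOX 10.5-fold, LMNB1 10.1-fold and the integrin subunit ITGB8 10.1-fold lower.

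Division genes had medians of -2.60 for G2/M, -1.75 for S phase and -1.69 for recombination and Fanconi genes in RS, each below every random list. In the last list 12 of 14 were at least 2-fold lower, including the helicase BLM at 5.12-fold. CDC45, a part of the replicative helicase, was 9.41-fold lower, E2F8 7.32-fold, MKI67 4.21-fold and CDC25A 1.76-fold. CCNE1 was 1.08-fold higher. Lamina and chromatin architecture genes had a median of -0.63, below every random list, with 8 of 28 at least 2-fold lower. HMGB2 was 7.83-fold lower and the lamina-associated TMPO 5.17-fold. Of the cell cycle inhibitors, CDKN2A was 2.58-fold, CDKN2B 1.66-fold and CDKN1A 1.36-fold higher, while CDKN1B was 2.52-fold and CDKN1C 2.07-fold lower. Their list had a median of 0.11 at percentile 75.3, and the p53 target list one of 0.20 at percentile 97.2, with PLK3 the 1 member past 2-fold, and the p53 list stood above the range under 5 alternatives, up to percentile 98.8.

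Histone lysine methyltransferases had a median of -0.33 at percentile 0.46 in RS, with 3 of 27 at least 2-fold lower and none higher. EZH2 was 4.49-fold, NSD2 3.70-fold and KMT5C at least 2.02-fold lower, and KMT5A was 1.61-fold lower, while EZH1 was 1.69-fold and SETD7 1.42-fold higher. With a higher floor that list sat on the limit, at percentile 2.5. Polycomb genes had a median of -0.30 at percentile 0.8, with EZH2 and PHF19, at 2.19-fold, the members past 2-fold. Their position was lost with all probe sets of each gene, at percentile 25.6, and without cross-hybridizing probe sets, at 25.4. Mitochondrial ribosomal protein genes had a median of -0.17, below every random list, with none of 68 past 2-fold. MRPL11 was 1.67-fold lower and MRPL2 1.41-fold higher.

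Cytokine and chemokine genes had a median of 0.00 at percentile 58.4 in RS, with 2 of 24 at least 2-fold higher and 3 lower. CXCL12 was 2.70-fold and CXCL8 2.35-fold higher, IL6 was 1.59-fold higher, and TSLP was 5.48-fold, IL1B 4.68-fold and CXCL5 2.60-fold lower. NF-kappaB targets had a median of -0.38 at percentile 0.41, with 4 of 20 lower and 1 higher. TNFAIP6, a hyaluronan-binding protein of inflamed tissue, was 8.75-fold lower, TNFAIP8 2.49-fold lower and NFKBIZ 2.73-fold higher. Without cross-hybridizing probe sets that list was inside the range, at percentile 6.04. Secreted proteases had a median of 0.13 at percentile 75.2, with ADAMTS5 3.08-fold and TIMP3 2.62-fold higher and MMP1 3.96-fold lower. Growth factors and IGF-binding proteins had a median of 0.41, above every random list, with 7 of 29 higher and 2 lower. ANGPTL4 was 7.04-fold, NRG1 4.67-fold and PDGFB 4.32-fold higher, and IGFBP2 was 3.10-fold lower.

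Among the lists fixed in advance, the signaling list with the highest median in RS was that of TGF-beta targets, at 0.84. That lay above every random list, with 7 of 17 at least 2-fold higher and none lower. The inhibitors of differentiation ID1, ID2 and ID3, which are also BMP targets, were 5.99-fold, 2.80-fold and 3.71-fold higher and SMAD7, a feedback inhibitor, 4.77-fold, while TGIF1 was 1.88-fold lower. Ras and MAPK feedback genes had a median of 0.28 at percentile 99.9 with 6 of 28 higher. DUSP4 was 4.87-fold, EGR3 at least 4.61-fold and DUSP6 1.77-fold higher, and LIF was 1.95-fold lower. Interferon-stimulated genes had a median of 0.32 at percentile 99.98 with 4 of 33 higher, IFI27 at 4.88-fold, MX1 at least 4.61-fold, IFI6 at 3.27-fold and ISG15 at 2.29-fold. With a higher floor that median was 0.04 at percentile 82.0, and without cross-hybridizing probe sets it was at percentile 93.9. AP-1 genes had a median of 0.23 at percentile 96.9, and stood above the range after quantile normalization, at 99.2, and with no filter on low values, at 98.8. Notch genes had a median of 0.04, with none of 12 past 2-fold.

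Contractile and cytoskeletal genes had a median of 0.29 at percentile 99.9 in RS. LMOD1 and CNN1, proteins of smooth muscle filaments, were 2.94-fold and 2.35-fold higher, ACTA2, smooth muscle actin, was 1.81-fold higher, and MYH10 was 2.24-fold lower. Lysosome genes had a median of 0.25 at percentile 99.9 with 4 of 36 higher and 1 lower. FUCA1 was 2.60-fold and the cholesterol transporter NPC1 2.07-fold higher, and CTSH was 2.22-fold lower. Autophagy genes had a median of 0.31 at percentile 99.9, with none past 2-fold and MAP1LC3B 1.79-fold higher. NRF2 and antioxidant genes had a median of -0.12 at percentile 1.61, with NQO1 2.59-fold and SLC7A11 2.33-fold lower and GPX3 3.74-fold higher. Without cross-hybridizing probe sets this list was at percentile 5.27.

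The remaining lists lay inside the range of random lists in RS, of which 4 moved below it under 1 alternative each. Medians were 0.02 for collagens, where COL11A1 was 3.53-fold higher and COL5A3 4.42-fold lower, and 0.15 for other extracellular matrix genes, with POSTN 27.2-fold lower. They were -0.02 for the unfolded protein response, -0.04 for the BCL2 family, 0.20 for heat shock proteins and 0.21 for glycolysis. ASNS, which makes asparagine, was 4.13-fold lower and the small heat shock protein HSPB8 2.49-fold higher. Complex I had a median of 0.07, complexes II to V of 0.02, the tricarboxylic acid cycle of -0.09, fatty acid oxidation of -0.03 and cholesterol synthesis of 0.02. COX7A1, a muscle-type subunit of cytochrome c oxidase, was 3.54-fold higher. Cytosolic ribosomal proteins had a median of 0.04, which was -0.09 at percentile 2.19 after quantile normalization, ribosome biogenesis genes of -0.11, aminoacyl-tRNA synthetases of -0.09 and proteasome subunits of -0.04. The synthetases were at percentile 2.39 after quantile normalization, and the ribosome biogenesis and tricarboxylic acid cycle lists at 2.37 with all probe sets of each gene. Marker medians were 0.04 for fibroblasts, 0.00 for blood cells, 0.24 for endothelial cells, 0.22 for neural cells and -0.04 for epithelial cells, where KRT8 was 2.20-fold and KRT18 2.01-fold higher. With a higher floor the epithelial median in RS was 0.64 at percentile 99.3.

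HRAS was 3.01-fold lower in RS on its 1 probe set, with signals of 7696 in growing cells and 2553 in RS. In all, 7 of 42 lists stood above and 9 below the range of random lists, against 1.05 on each side if genes varied independently. A second probe set gave the same sign for 91.0% of 581 genes past 2-fold. Dim probe sets, below the floor on both arrays, again count as 0.00 in the median of all probe sets. With the median of all probe sets the log2 ratio in RS was 0.00 for ITGB8, -2.52 for POSTN, -1.48 for HMGB2, 2.39 for TMEM178B, 1.83 for TENM1, 1.60 for SYNPO2 and 0.91 for CDKN2A, and HMGB2 was at 0.00 without cross-hybridizing probe sets.

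**Figure D2:**
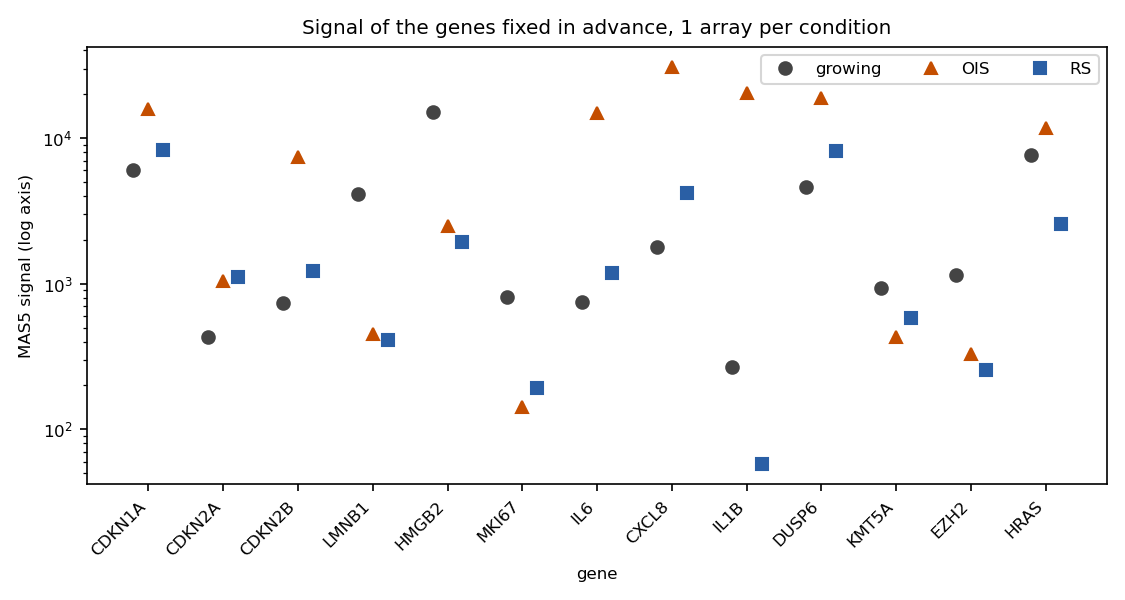
Signal of each gene fixed in advance on the growing, OIS and RS arrays, with 1 point per array on a log axis. LMNB1 is at 4163 in growing cells, 450 in OIS and 411 in RS, whereas IL1B is at 269, 20515 and 57.6.

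The third comparison set OIS against RS and asked how the transcriptomes of cells arrested by different routes differ. The inflammatory secretome separated them. Cytokine genes had a median log2 ratio of 2.95 for OIS over RS with 16 of 24 at least 2-fold higher, and NF-kappaB targets of 1.58 with 16 of 20 higher and none lower, both above every random list. RS had the higher levels of contractile genes, with a median of -0.42 for OIS over RS. Across all genes 738 were at least 2-fold higher in OIS and 709 at least 2-fold lower, with 188 and 139 past 4-fold.

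Ranked by the same rule, IL1B had the largest ratio of OIS over RS, 356-fold higher in OIS. It was followed by CXCL5 at 222-fold, TNFSF15 at 132-fold, PTGS2 at 128-fold and CXCL1 at 102-fold. The RS signals of IL1B and CXCL5, 57.6 and 46.4, were near the floor. With the floor at the 60th percentile their log2 ratios were 7.85 and 6.86 in place of 8.48 and 7.79. POSTN was 59.5-fold, GABRA2, a GABA receptor subunit, 44.1-fold, ITGB8 27.5-fold, the sulfotransferase CHST2 24.4-fold and TNFAIP6 23.6-fold higher in OIS. At the other end NOG, which encodes the BMP antagonist noggin, was 33.3-fold lower in OIS, with signals of 135 in OIS and 4506 in RS. OXTR was 28.2-fold, ANKRD1 24.0-fold, SYNPO2 19.4-fold, the phospholipid flippase ATP10A 15.6-fold and TENM1 13.6-fold lower. The pregnancy-specific glycoprotein PSG5 was 12.2-fold, the hepatocyte growth factor receptor MET 11.8-fold, the neurexin NRXN3 11.8-fold and the growth factor FGF1 11.3-fold lower in OIS. Other probe sets of MET and FGF1 gave log2 ratios as small as -0.83 and -0.91, and with the median of all probe sets the ratio was -0.21 for ATP10A, -0.50 for MET, 0.00 for ITGB8, 1.91 for CDKN2B and 4.12 for CXCL8. Probe sets below the floor on both arrays count as 0.00 in that median. The CXCL5 ratio was 1.28 with cross-hybridizing probe sets left out.

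Of the genes fixed in advance, IL6 was 12.5-fold, CXCL8 7.37-fold, CDKN2B 5.99-fold, HRAS 4.60-fold, DUSP6 2.28-fold and CDKN1A 1.91-fold higher in OIS than in RS. LMNB1 was 1.10-fold, HMGB2 1.29-fold and EZH2 1.28-fold higher in OIS than in RS. CDKN2A was 1.07-fold, MKI67 1.35-fold and KMT5A 1.35-fold lower in OIS. The lamina and division markers among these genes differed less between OIS and RS than IL6 and CXCL8 did.

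The other lists higher in OIS than in RS included signaling, secreted and stress genes, and those of the next sentences stood at percentile 99.6 or above. Interferon-stimulated genes had a median of 0.99 with 15 of 33 higher, and cell cycle inhibitors of 0.71 with 2 of 6 higher. Ras and MAPK feedback genes had a median of 0.53 with 13 of 28 higher and 2 lower, and AP-1 genes of 0.44 with 5 of 19 higher and 3 lower. LIF was 8.15-fold, ISG20 at least 4.39-fold and IER3 6.03-fold higher in OIS, while DUSP1 was 2.80-fold and KLF4 5.08-fold lower. Growth factors had a median of 0.41 with 10 of 29 higher and 4 lower, secreted proteases of 0.42 with 5 of 18 higher and 3 lower, collagens of 0.24 with 5 of 24 higher and 2 lower, p53 targets of 0.27 with 2 of 24 higher and the unfolded protein response of 0.30 with 5 of 28 higher. GDF15 was 12.8-fold, MMP1 7.44-fold, COL5A3 9.46-fold and TRIB3 3.37-fold higher in OIS, and TIMP3 was 3.25-fold lower. Mitochondrial ribosomal protein genes had a median of 0.17 at percentile 99.6, which was 74.0 without cross-hybridizing probe sets. Polycomb genes had a median of 0.25 at percentile 97.6, a position lost under 6 settings, and endothelial markers one of 0.69 at percentile 98.7, lost under 4.

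Contractile genes had a median of -0.42 for OIS over RS, below every random list, with 5 of 28 at least 2-fold lower in OIS. CNN1 was 5.30-fold, LMOD1 5.12-fold and TAGLN 3.24-fold lower. S phase genes had a median of -0.25 at percentile 0.46 and G2/M genes of -0.23 at percentile 0.61, with none of the 40 G2/M genes past 2-fold. Both positions ended without cross-hybridizing probe sets, at percentiles 2.87 and 4.02. The lists of TGF-beta targets, lysosome, autophagy and lamina genes lay inside the range, with medians of 0.07, 0.08, 0.01 and 0.14.

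The last comparison asked how far the differences from growing cells were shared by OIS and RS. At least 2-fold higher in both were 144 genes and at least 2-fold lower in both 405, against 24.7 and 49.8 for independent lists. Of the 97 measured genes in the S phase, G2/M and recombination lists, 84 were among the 405. DUSP4, ANGPTL4, IFI27 and CDKN2A were higher in both, and LMNB1, HMGB2, EZH2, TOX and SPC25 lower in both. In opposite directions were 26 genes higher in OIS and lower in RS, such as IL1B, POSTN and ITGB8, and 31 lower in OIS and higher in RS, such as NOG and CXCL12, against 37.0 and 33.2 for independent lists. Across genes, which are not independent replicates, the log2 ratios had a correlation of 0.46, and of 0.42 without the 3 division lists.

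Both ratios share the growing array, so part of this overlap may come from that array, and 1 control array could not be divided. In 100 simulations of unchanged arrays with the noise of the closest pair of arrays, RS and growing cells, the mean overlap was 231 higher and 349 lower, with at most 269 and 389, against 144 and 405 observed. These simulations called 770 genes higher and 776 lower in each ratio, against 663 and 501 observed higher and 893 and 751 observed lower. The overlaps were not matched for these numbers, so neither was shown to differ from that of a shared control array. Opposite differences, counted after the data were seen, averaged 10.5 and 9.99 in the simulations with at most 17 and 19, below the 26 and 31 observed. The simulations had a correlation of 0.50 and a covariance of 0.224, against an observed covariance of 0.223. Equal noise on arrays that share a control gives a correlation near 0.50 by construction, whatever the size of the noise. The simulated covariance follows from the size of the noise put in. Neither value therefore shows where the observed agreement comes from. The noise of the closest pair includes all real differences between RS and growing cells and is an upper bound. With probe error alone as noise, a simulation added after the data were seen, the means were 29.5 and 30.6, with at most 43 in either direction, and the covariance was 0.062, which is 0.161 below the observed value.

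**Figure D3:**
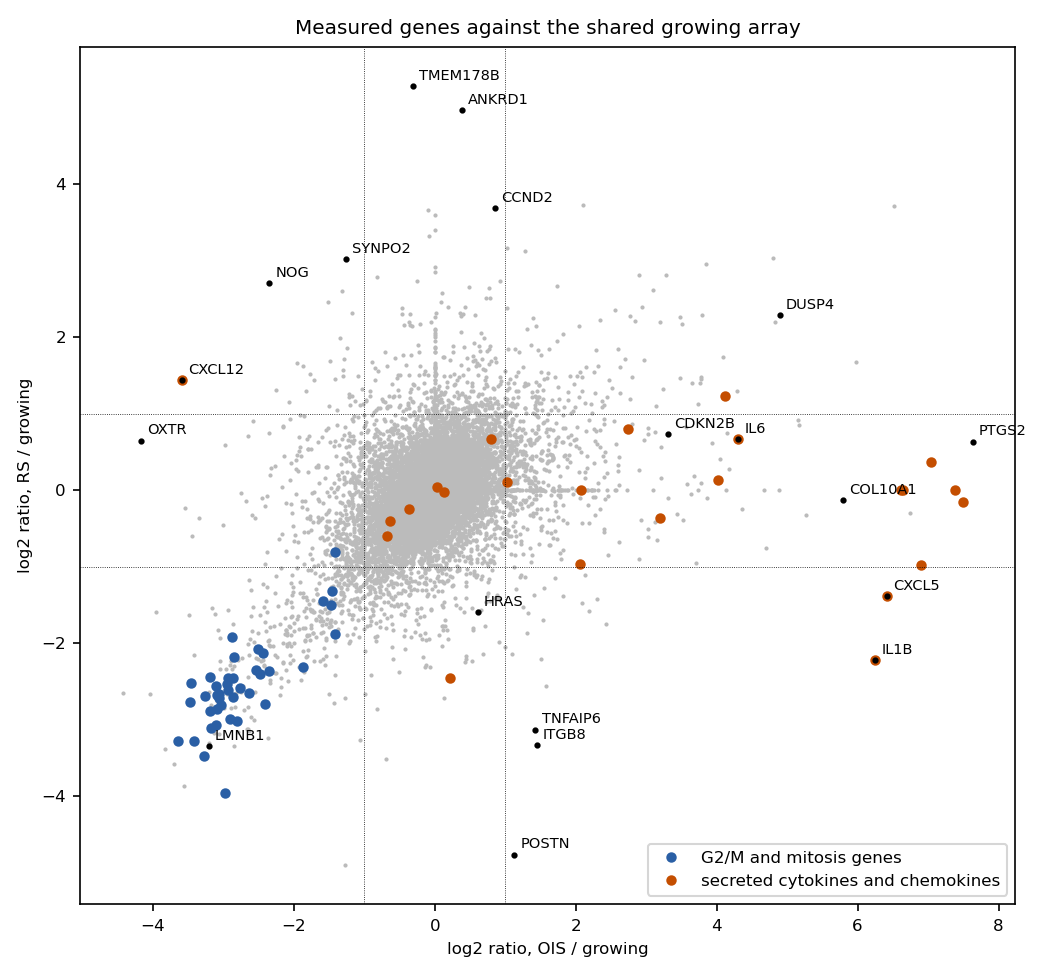
Log2 ratio of each measured gene in OIS over growing cells (horizontal) and in RS over growing cells (vertical), with G2/M genes and cytokine genes colored, 2-fold limits dotted and selected genes named. The G2/M genes lie low on both axes, while IL1B is high in OIS at 6.25 and low in RS at -2.23.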

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

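The tests of blood cell markers, of endothelial markers and of scaling given here were chosen only after the result was seen. With 1 array per condition none of the differences between OIS and RS named here was tested. They stand out because the ratio to growing cells was at least 2-fold in both states but in opposite directions for genes, and outside the range of random lists on opposite sides for gene lists.

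Only the genes ranked highest or lowest in a comparison and those fixed in advance were searched. Across all measured genes, 26 were higher in OIS and lower in RS, and 31 the reverse. Of the genes searched, IL1B, CXCL5, POSTN, ITGB8 and TNFAIP6 were higher in OIS and lower in RS than in growing cells. Their log2 ratios of OIS over RS were 8.48, 7.79, 5.90, 4.78 and 4.56. Lower in OIS and higher in RS were NOG at -5.06, SYNPO2 at -4.28, ATP10A at -3.96, PSG5 at -3.61, NRXN3 at -3.56 and FGF1 at -3.50. With the median of all probe sets, only 4 of these 11 genes, IL1B, TNFAIP6, NOG and PSG5, kept both 2-fold differences from growing cells. In that median OIS over RS was at 0.00 for ITGB8 and -0.21 for ATP10A. Both genes had only 1 probe set above the floor on both the OIS and RS arrays. Probe sets below the floor on both arrays count as 0.00, so these small values are no disagreement between bright probe sets. With cross-hybridizing probe sets left out, 8 of the 9 genes with a value kept both, and CXCL5 did not. SYNPO2, ATP10A and NRXN3 encode an actin-associated protein, a phospholipid flippase and a synaptic adhesion protein. The list of NF-kappaB targets had a median of 1.58 for OIS over RS, and the list of contractile genes one of -0.42. Without cross-hybridizing probe sets the NF-kappaB list in RS was at percentile 6.04 and the contractile list in OIS at 3.62, so neither list then stood apart on both sides. Probe sets without a single gene name were not used for genes. Of 13522 such probe sets 5040 were above the floor on at least 1 array, 159 were at least 2-fold higher and 208 lower in OIS than in growing cells, and 193 higher and 153 lower in RS.

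The high cytokine and NF-kappaB genes of the OIS array were weighed against technical sources. Blood cells in the culture would bring their own transcripts, but blood cell markers had a median log2 ratio of -0.0802 for OIS over growing cells. After quantile normalization the NF-kappaB list median was 1.30. The arrays were already alike in trimmed mean and median, and that step again makes arrays alike. It cannot show a shift that the scaling had removed, so it does not decide on scaling. Endothelial cells are argued against because all 12 endothelial markers had a median signal of 24.9 on the OIS array, and 7 were below the floor on every array. The 5 measured ones, however, had a median log2 ratio of 1.13. Ras activation stays an untested hypothesis, since 1 culture per condition was measured and 4-OHT without the fusion was not analysed here.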

How the results depend on the processing

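The simulation with probe error as noise was the only alternative chosen after seeing the data. No named gene past 2-fold and no list outside the random range took the opposite sign under any alternative. Of 990 list medians under alternatives 905 stayed closer to their main value than the SD of random list medians, and 85 moved farther. Of 746 ratios of named genes 675 stayed closer to their main value than the SD between probe sets, and 71 moved farther. Of 55 positions of lists outside the random range, 14 were lost under some of the 8 settings and 41 under none. Lists with fewer than 5 measured genes in a setting were not scored there, and their positions counted as not lost. This occurred with the floor at the 60th percentile and without cross-hybridizing probe sets, so not all of the 41 were tested under every setting. No scaling moved the higher share of calls by more than 10 percentage points, the farthest being 48.1% against 42.6% in OIS after quantile normalization. Counts depended most on the floor and on the size asked for. With the floor at the 25th percentile, which admits dim probe sets, 1543 genes were higher and 1698 lower in OIS than growing, 1317 and 1614 in RS, 1731 and 1579 in OIS against RS, and 460 higher and 737 lower in both states. At 3-fold, a stricter size by construction, these were 291 and 342, 147 and 317, 305 and 252, and 32 and 194. With the median of all probe sets 322 genes were higher in RS and 85 in both states, and the correlation of ratios was 0.486. It was 0.483 with the floor at the 60th percentile. Lists below the random range in OIS against RS numbered 5 without a floor and 1 without cross-hybridizing probe sets. Those gained without a floor were epithelial markers, at -0.81 and percentile 0.11, and neural markers, at -0.75 and percentile 0.825. In the main setting these lists were at percentiles 51.4 and 3.06. With the floor at the 60th percentile the epithelial list was at -0.95 and percentile 0.22. For these last values the cause was not tested. No paired analysis was possible because each group had 1 array.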

Other observations

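The gene lists in this part and the tests of HRAS, its neighbours, ESR1 and the RS histone values were chosen only after the results were seen, and genes named here were picked after their values were seen. A list of 14 BMP targets and antagonists had a median log2 ratio of 1.69 in RS over growing cells, above every random list, with 9 genes at least 2-fold higher and none lower. The list was made because some of its genes were high in RS, and its 7 genes not seen before had a median of 0.36 at percentile 97.31, inside the range, and at 98.4 after quantile normalization, above it. In OIS over RS these 7 had a median of -0.42 at percentile 2.31, below the range, and at 1.93 after quantile normalization. Without cross-hybridizing probe sets they were inside the range in both comparisons, at percentile 2.63 for OIS over RS and 97.495 for RS over growing cells. The position of the whole list thus rests in part on the genes that prompted it. For all 14 genes the OIS median was -0.29, with 1 higher and 3 lower, and OIS over RS gave -2.02. ID1 had a log2 ratio of 2.58 in RS, the BMP-binding protein BMPER 2.38, ID4 2.31, SMAD7 2.25 and the transcription factor ATOH8 2.16. NOG, an antagonist of the same pathway, had 2.71 in RS and -2.35 in OIS, and SMAD9 was at 0.36 and -2.04, while the antagonist GREM1 was at -0.60 and -0.23.

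Pregnancy-specific glycoprotein genes, placental genes of the carcinoembryonic antigen family, had a median of 1.32 in RS with 7 of 9 at least 2-fold higher, and of -1.06 in OIS with 6 lower. PSG4 was at 1.32 and -1.04 and PSG6 at 1.69 and -1.49. These paralogs share probe sequence, and only 2 had other probe sets, so they cannot be read as separate genes. HLA class I and antigen presentation genes had a median of 0.54 in OIS, above every random list, with 1 of 15 at least 2-fold higher, and of 0.14 in RS at percentile 85.0. Without cross-hybridizing probe sets the OIS median was 0.31. HLA-F was at 1.14 in OIS and 0.19 in RS.

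HRAS was 3.01-fold lower in RS than in growing cells, and the Ras fusion of these cells is joined to a part of the estrogen receptor gene ESR1. Quantile normalization left HRAS at -1.62. That step makes arrays alike, as the scaling had already done, so it does not decide on scaling. The 20 measured genes nearest to HRAS on chromosome 11 had a median of 0.313 and none was 2-fold lower, which argues against loss of that segment. Of 9 ESR1 probe sets 5 were above the floor in growing cells, all 5 were lower in RS with a median of -1.14, and all 5 were higher in OIS with a median of 0.52. All 5 are of the kind called cross-hybridizing, so none remained when such probe sets were left out. Their signals in growing cells ran from 592.7 down to 65.9, the latter near the floor. Being read from the same arrays, they are not separate observations of the cultures. A lower level of the fusion transcript after long passage is a candidate explanation, but whether these probe sets detect the fusion was not established.

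Replication-dependent histone genes were higher although S phase genes were lower, with a median of 0.61 in OIS and 0.79 in RS over 27 measured genes, of which 6 and 11 were at least 2-fold higher. In OIS the median was 0.553 after quantile normalization but 0.156 without cross-hybridizing probe sets, so sharing of probes between paralogs may account for the OIS value. In RS it was 0.782 over 19 genes without them, so the RS value did not rest on those probe sets alone. Sharing among the remaining probe sets was not tested. H4C5, the gene at that median, had signals near the floor, 50.3 in growing cells and 86.5 in RS. H4C8 was at 1.82 in OIS and 2.04 in RS, and H2AC6 at 0.71 and 1.58, both on cross-hybridizing probe sets. Whether polyadenylated histone transcripts of arrested cells contribute was not tested.

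ANKRD1 is a target of the YAP and TEAD transcription factors, so other targets were examined. Without ANKRD1, 20 measured targets had a median of 0.23 in RS at percentile 96.77. Without cross-hybridizing probe sets the median was 0.47 over 17 genes at percentile 99.98, but after quantile normalization the percentile was 95.89, which leaves open whether they were higher as a group. In OIS over growing cells their median was -0.23 at percentile 0.47, and at 8.88 without cross-hybridizing probe sets, so the OIS over RS median of -0.64, below every random list, is no sign of higher levels in RS alone. A further hypothesis was that zinc finger genes of chromosome 19 were lower in RS than zinc finger genes elsewhere. Their medians were -0.139 over 182 genes and -0.184 over 190, and 16.31% of random divisions gave a higher difference, so the data argue against it.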
